A study of Mus musculus with 12 samples.

How the data were processed

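RNA sequencing libraries of sorted mouse cells were analysed in 4 groups of 3. Per the labels, the first pair of groups held TOM positive and TOM negative cells sorted from the hypothalamus of Mc4r-Cre; Ai14 mice aged 4 weeks. The second pair held cells sorted from the paraventricular nucleus of the hypothalamus (PVH) of Otp fl/fl; Ai14 mice aged 26 weeks, dissected 12 weeks after injection of an adeno-associated virus (AAV). TOM positive cells were sorted after AAV-Cre and GFP positive cells after AAV-GFP. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Per the labels' protocols, cells were sorted into Trizol and libraries were made with a SMART-Seq mRNA kit for low input, and no protocol describes molecular identifiers. PCR copies are therefore counted as reads, and every interval and every lower bound below covers counting error only.

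The deposited values were whole-number counts of reads per gene symbol, not normalized. Per the submitters' processing notes, reads went through FastQC, Trim Galore, STAR and featureCounts, with no versions. Per the file headers of the AAV libraries, the authors counted read pairs with featureCounts 2.0.1 per gene name on the GENCODE vM30 annotation. Those headers set no strand and allow neither multi-mapping reads nor reads over several genes. The table of the TOM libraries has no such header, so its counting settings are not given in the sources used here. Both tables list the same 55809 gene symbols. The 6 single AAV files were identical to their columns in the joint table. The submitters' notes name the mm10 build. The annotation in the headers belongs to a later mouse assembly. Of 50664 symbols shared with the GENCODE vM21 annotation, 45334 had no base in common with their position there, and 5719 of these had at least 1000 counts in some library. Coordinates are therefore those of the vM30 annotation as the files give them, and none was converted. Counting without strand cannot separate a gene from an antisense partner. Genes with near-identical copies, such as the hemoglobin, Hspa1a and Hspa1b and H2 genes, are uncertain because reads that map to several places were left out. There were 17 symbols listed on more than 1 chromosome.

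Library totals ran from 13506018 to 27827853 counts. Each comparison was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter at its default minimum count of 10, and the quasi-likelihood test. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM values were computed from the deposited counts and the TMM-scaled library totals. Values are given as mean ± SD over 3 libraries, and log2 fold changes as estimate ± SE, where the SE was derived from the quasi-likelihood F statistic. Where all 3 libraries of a group held 0 counts, the fold is a lower bound computed against 3 counts over the group. Where a group held 1 to 3 counts, the ratio of summed counts is given with its exact 95% interval.

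Before the data were examined, 27 gene lists were fixed, covering hypothalamic neurons, other cell types and cell states. Lists with at least 3 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. List membership is by gene symbol, and some genes stand in 2 lists. The rule for named genes was fixed at the same time. It takes Mc4r, Otp and Sim1, and the 6 largest changes per direction among genes that passed, did not overlap between groups, had a mean of at least 10 CPM in the higher group and had no predicted or clone name. It also takes the 3 members with the smallest p of each list of neuronal or energy-balance genes and the 2 with the smallest p of each list of cell-type or cell-state genes. Genes outside this rule are said to be so. Some genes that the rule takes are not reported here, and their values were left out of the comparison of settings.

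The settings tried were RLE size factors, no count filter, a replicate block, each library left out, mitochondrially encoded genes removed, DESeq2 1.42.0, voom with quality weights, robust dispersion and a test against a 1.5-fold change. Library totals without scaling factors, thinning to equal depth and a gene set without glial, vascular, ependymal and blood genes were added after seeing the data. No library pair of a group agreed within sampling noise, since the chi-square per degree of freedom was 47.7 or more in each. The steps were tested on simulated data drawn from the real means and library sizes. The genes changed in them were drawn only from those above a minimum mean CPM, which Mc4r, Otp and Sim1 did not reach. The recovered shares below therefore do not describe genes at such low counts. With 3 libraries per group, the TOM fit of 14403 genes recovered 12, 44, 78 and 98% of the genes changed by 2, 4, 8 and 16 times, and the AAV fit of 14615 genes recovered 0, 12, 68 and 86%. An exact permutation test of 3 libraries against 3 cannot go below p = 0.10, so none is given. Of 127 calls in the simulated TOM comparison 11 were false, and of 89 in the simulated AAV comparison 6 were false. Figures were drawn with matplotlib 3.10.9.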

Results

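The data were gene counts of 12 libraries in 4 groups of 3. In Mc4r-Cre; Ai14 mice, Cre made in cells that use the Mc4r gene switches on the red reporter tdTomato (TOM), and sorting gave TOM positive and TOM negative hypothalamic cells. Mc4r encodes the melanocortin 4 receptor, which restrains food intake. The study asked which transcription factors regulate this gene. In Otp fl/fl; Ai14 mice, a virus carrying Cre deletes the floxed Otp gene and switches on TOM, and a virus carrying GFP served as the control. Otp encodes a homeodomain transcription factor of hypothalamic neurons. Totals were 17727134, 26693043 and 27827853 counts in TOM positive replicates 1, 2 and 3 and 22379648, 23002571 and 22956506 in the TOM negative ones. The AAV-Cre libraries held 15125868, 14375742 and 13506018 counts, and the AAV-GFP libraries 19245171, 14545566 and 16075063. Gene coordinates are those of the GENCODE vM30 annotation in the files.

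The first comparison asked what set TOM positive cells apart. As lists, tested with camera at its preset correlation, neuronal, synaptic and oligodendrocyte mRNAs were higher in TOM positive cells, and microglial, vascular and blood mRNAs were lower. No list passed with an estimated correlation (camera adjusted p of 0.12 or more). The median log2 fold change was 2.44 over pan-neuronal genes, 1.24 over oligodendrocyte genes and -5.44 over microglial genes. Of 15228 genes tested with edgeR, 3635 passed the threshold, 1589 higher and 2046 lower in TOM positive cells. The 2 groups did not overlap for 46.4% of the genes tested, where chance gives 10%. Without scaling factors, 2204 genes were higher and 1532 lower, and the fold changes shifted by a median of 0.26 on the log2 scale. The count was 1511 without TOM negative replicate 2, 1987 with a replicate block and 2177 when tested against a 1.5-fold change. Of the 67 genes named by the rule that passed, 47 passed in all 6 fits with 1 library left out, and those named below are among them unless said otherwise. Counts adjusted over the list alone equalled those over all genes in this comparison where none is given.

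Mc4r (chromosome 18, 66990775 to 66993577, minus strand) was counted in 1 of the 3 TOM positive libraries, with 63 counts in replicate 1 and 0 in replicates 2 and 3, and had 0 counts in each TOM negative library. Otp (chromosome 13, 95012110 to 95021638, plus strand) had 36, 27 and 1 counts in the TOM positive libraries and 0 in each TOM negative library. Summed over the groups, Mc4r was at least 16.6-fold and Otp at least 16.9-fold higher in TOM positive cells, by counting error alone. Both bounds rest on replicate 1, without which Mc4r had no count and Otp was at least 9.8-fold higher. Without replicate 3, Otp was at least 26.8-fold higher, and without replicate 2 or 3 Mc4r was at least 26.4-fold or 26.8-fold higher. Sim1 (chromosome 10, 50770850 to 50865248, plus strand), which encodes a transcription factor of PVH neurons, had 0 counts in all 6 libraries. None of the 3 entered the test, since Mc4r, Otp and Sim1 were too low for the count filter. Without that filter, the edgeR adjusted p was 0.21 for Mc4r and 0.11 for Otp, so neither difference passed.

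Among 20 pan-neuronal genes, 10 rose, 0 fell and 10 did not pass, with 12 that rose when adjusted over the list alone. The list had a median log2 fold change of 2.44 (camera adjusted p = 4.2e-06, and adjusted p = 0.15 with an estimated correlation). Celf4, which encodes an RNA-binding protein of neurons, averaged 88.2 ± 24.6 CPM in TOM positive and 4.80 ± 1.27 CPM in TOM negative cells (SD, n = 3 each), a log2 fold change of 4.20 ± 0.35 (edgeR adjusted p = 0.000411). Elavl3, another neuronal RNA-binding protein gene, rose by 2.73 ± 0.29 (edgeR adjusted p = 0.00102). The list took 0.0937% ± 0.0144 of the counts in TOM positive and 0.0228% ± 0.00284 in TOM negative libraries.

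Of 24 tested synaptic vesicle genes, 12 rose and 1 fell (median log2 fold change 1.66, camera adjusted p = 6e-05, and adjusted p = 0.12 with an estimated correlation). Snap25, a membrane fusion protein gene of nerve terminals, rose by 3.59 ± 0.54 on the log2 scale, and by 4.28 without TOM negative replicate 1, and Syn1, which tethers vesicles, by 1.80 ± 0.28. The member that fell was Syngr1, with a log2 fold change of -1.99 ± 0.20. Of 22 voltage-gated channel genes 3 rose, the potassium channel genes Kcna1, Kcna2 and Kcnq3 (camera adjusted p = 0.028, and adjusted p = 0.21 with an estimated correlation). Without scaling factors that list did not pass (camera adjusted p = 0.057). Kcna1 had a log2 fold change of 2.88 ± 0.43, while Kcna2 was lost in 4 fits with 1 library left out and Kcnq3 without TOM negative replicate 2 (edgeR adjusted p up to 0.077 and 0.051). Of 16 genes for peptide processing and dense-core vesicles 3 rose, or 1 when adjusted over the list alone (camera adjusted p = 0.0079, and adjusted p = 0.21 with an estimated correlation). Syt4, a vesicle protein gene, had a log2 fold change of 4.17 ± 0.58, and Ptprn and Sez6l2 lost their calls in all 6 fits with 1 library left out (edgeR adjusted p up to 0.16 and 0.14). Slc17a6, which encodes the vesicular glutamate transporter of hypothalamic neurons, had 132, 126 and 129 counts against 0, 0 and 1, a ratio of summed counts of 306 after scaling with an exact 95% interval of 54.6 to 12100 (edgeR adjusted p = 0.00661). Of 4 glutamatergic genes 2 rose, among them Slc17a6 (camera adjusted p = 0.032, and adjusted p = 0.30 with an estimated correlation). That list did not pass without TOM negative replicate 1 or without scaling factors (camera adjusted p of 0.061 and 0.052).

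Of 12 PVH neuropeptide genes tested, 3 rose, and the list did not pass (camera adjusted p = 0.097). Tac1, the substance P precursor, averaged 39.1 ± 25.9 CPM against 3.28 ± 1.34 CPM, a log2 fold change of 3.57 ± 0.60 (edgeR adjusted p = 0.00683). It rests in part on TOM positive replicate 1, with 1344 counts against 771 and 665 in replicates 2 and 3, and was 2.88 without that library (edgeR adjusted p = 0.019). Vgf and Cck, the precursors of other secreted peptides, also passed, and each lost its call in 4 of the 6 fits with 1 library left out, with edgeR adjusted p up to 0.073 and 0.11. Those fits were the ones without TOM positive replicate 1 or without any of the TOM negative libraries. Of 25 hypothalamic transcription factor genes tested, 2 rose, or 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.15). Tcf7l2, a mediator of Wnt signalling, had a log2 fold change of 1.65 ± 0.22 (edgeR adjusted p = 0.00281), and Peg3, an imprinted gene, lost its call in 5 fits with 1 library left out (edgeR adjusted p up to 0.12). The TOM positive libraries also held more oligodendrocyte mRNA, given below, so which cells held Tcf7l2 mRNA cannot be told. Of 23 axon guidance genes 3 rose, in a list that did not pass (camera adjusted p = 0.14). Sema5a and Unc5c had log2 fold changes of 3.45 ± 0.46 and 3.36 ± 0.68, and Efnb3 lost its call without TOM negative replicate 2 (edgeR adjusted p = 0.055). Of 7 energy-balance receptor genes 2 fell. Ntrk2, the receptor of brain-derived neurotrophic factor, had a log2 fold change of -0.93 ± 0.14, and Ptger3, a prostaglandin receptor gene, had 0 counts in each TOM positive library and was at least 191-fold lower. The list of energy-balance receptors did not pass, with a median of 0.00 (camera adjusted p = 0.52). Of 16 monogenic obesity genes, Ndn and Phip rose and Ntrk2 fell (camera adjusted p = 0.37). Of 5 monoaminergic and cholinergic genes, Ddc and Slc18a2 rose (camera adjusted p = 0.23). Ndn, Phip, Ddc and Slc18a2 each lost their calls in 3 or more fits with 1 library left out, with edgeR adjusted p up to 0.10, 0.11, 0.069 and 0.14. None of 4 GABAergic genes and none of 5 peptides of other hypothalamic nuclei passed with edgeR (camera adjusted p of 0.27 and 0.46). Of the lists in this paragraph, 4 passed, upward, without a count filter and without TOM positive replicate 2. These were PVH neuropeptides (camera adjusted p of 0.047 and 0.019), transcription factors (camera adjusted p of 0.032 and 0.027), axon guidance (camera adjusted p of 0.047 and 0.032) and GABAergic genes (camera adjusted p of 0.049 and 0.038). PVH neuropeptides also passed without TOM negative replicate 2 (camera adjusted p = 0.048), and transcription factors without TOM positive replicate 3 or TOM negative replicate 3 (camera adjusted p of 0.028 and 0.027).

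Oligodendrocyte genes took a larger share of the counts than any other marker list in the TOM positive libraries, 10.9% ± 0.70 against 2.80% ± 0.342 in the TOM negative ones. Of 15 such genes 13 rose, 14 when adjusted over the list alone (median log2 fold change 1.24, camera adjusted p = 1.9e-07, and adjusted p = 0.21 with an estimated correlation). Of 11 genes of oligodendrocyte precursors 5 rose, 6 when adjusted over the list alone, and Enpp6 rose by 2.59 ± 0.19 on the log2 scale (camera adjusted p = 0.0062, and adjusted p = 0.21 with an estimated correlation).

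Of 17 microglia and macrophage genes 16 fell (median log2 fold change -5.44, camera adjusted p = 1.5e-11, and adjusted p = 0.23 with an estimated correlation). Their share of counts was 0.0922% ± 0.039 against 3.20% ± 0.219. Trem2, a microglial receptor gene, averaged 11.1 ± 2.95 CPM against 703 ± 132 CPM. Havcr2 and Trpv2, the 2 named genes with the lowest fold changes, had 0 counts in each TOM positive library and were at least 1680-fold and 1640-fold lower. The hemoglobin genes, whose near-identical copies make single values uncertain, were among the 7 of 11 blood genes that fell (median -6.56, camera adjusted p = 1.2e-06, and adjusted p = 0.19 with an estimated correlation), and of 13 endothelial genes 8 fell (camera adjusted p = 0.00042, and adjusted p = 0.45 with an estimated correlation). Of 11 mural and fibroblast genes 3 fell (camera adjusted p = 0.032, and adjusted p = 0.34 with an estimated correlation), and that list did not pass without TOM positive replicate 3 or without TOM negative replicate 3 (camera adjusted p up to 0.098), or after thinning to equal depth (camera adjusted p = 0.074). Of 15 astrocyte genes 7 fell, among them Agt with a log2 fold change of -1.67 ± 0.20, in a list that did not pass (camera adjusted p = 0.069). Of 9 ependymal genes 2 fell, Rarres2 and Vim (camera adjusted p = 0.097), and Vim lost its call in 5 fits with 1 library left out (edgeR adjusted p up to 0.14). Without a count filter and without TOM positive replicate 2, the astrocyte list passed (camera adjusted p of 0.037 and 0.027), as did the ependymal list (camera adjusted p of 0.03 and 0.022). Astrocyte genes also passed without TOM negative replicate 1 (camera adjusted p = 0.03).

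Immediate early genes, which are induced within minutes of stimulation or tissue handling, were lower in TOM positive libraries. Those libraries also held less microglial, endothelial and blood mRNA, given above. Which cells held the mRNAs of the lists in this paragraph therefore cannot be told. Of 15 tested 12 fell, 13 when adjusted over the list alone, and 1 rose (median log2 fold change -3.21, camera adjusted p = 1.9e-07, and adjusted p = 0.12 with an estimated correlation). Junb, a transcription factor gene, averaged 120 ± 16.1 CPM against 1980 ± 175 CPM. The member that rose was Arc, named here after its values were seen, with a log2 fold change of 1.29. Of 17 unfolded protein and heat-shock genes 11 fell and 2, Hsph1 and Hsp90b1, rose (camera adjusted p = 0.0027, and adjusted p = 0.21 with an estimated correlation). Hsph1 and Hsp90b1, chaperone genes, were also named after their values were seen. Of 18 interferon and antigen presentation genes 10 fell, 11 when adjusted over the list alone (camera adjusted p = 4.3e-06, and adjusted p = 0.21 with an estimated correlation). B2m, the light chain of class I molecules, had a log2 fold change of -3.52 ± 0.20. Of 45 ribosomal protein genes 19 fell, 21 when adjusted over the list alone (median -0.62, camera adjusted p = 1.1e-05, and adjusted p = 0.46 with an estimated correlation), and of 10 mitochondrially encoded genes 8 rose, 9 when adjusted over the list alone (median 1.75, camera adjusted p = 4.3e-06, and adjusted p = 0.29 with an estimated correlation). Of 14 p53 response genes 2 rose and 3 fell, 4 when adjusted over the list alone (camera adjusted p = 0.91). Mdm2, which restrains p53, had a log2 fold change of 1.53 ± 0.25 and Cdkn1a, a cell cycle inhibitor gene, of -1.53 ± 0.28. In all, 16 of 27 lists passed, and with an estimated correlation 0 passed after adjustment, with 5 at an unadjusted p under 0.05 and 18 past the threshold with fry.

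**Figure D1:**
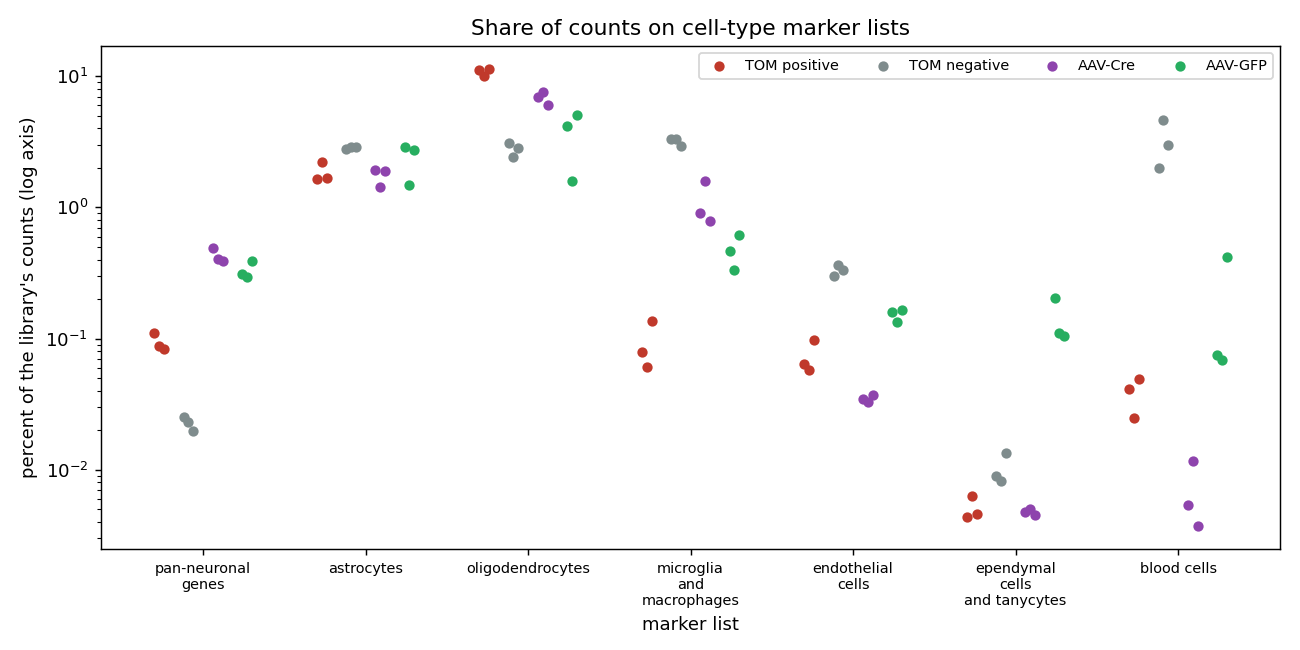
Share of each library's counts, in percent on a log axis, that fell on 7 cell-type marker lists, with 1 point per library and 1 colour per group. Oligodendrocyte genes took 10.9% of counts on average in TOM positive libraries, and ependymal genes took 0.00478% in AAV-Cre against 0.139% in AAV-GFP libraries.

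The second comparison asked what differed between PVH cells after AAV-Cre and after AAV-GFP. Of the 30 genes named by the rule that passed, 0 passed in all 6 fits with 1 library left out. Sst, Sez6l2, Mag, Csf1r, Emcn and Hspa1b passed in 0 of these fits, and Kcna1 in 1. The targeted gene came out in the direction of the labels. Otp had 12, 9 and 10 counts after AAV-Cre and 91, 102 and 38 after AAV-GFP, or 0.682 ± 0.0689 against 4.92 ± 2.37 CPM, a log2 fold change of -2.84 ± 0.87. Mc4r had 0 counts in each AAV-Cre library and 22, 11 and 13 in the AAV-GFP libraries, and was at least 14.7-fold lower by counting error alone. Each AAV-Cre library had more genes with no count than any AAV-GFP library. Few starting molecules therefore cannot be told apart from lower expression at such counts. Sim1 had 0, 26 and 22 counts against 18, 12 and 9 (log2 fold change 0.42 ± 1.40). Over all genes tested none of the 3 passed, with edgeR adjusted p of 0.134 for Otp, 0.0596 for Mc4r and 0.917 for Sim1. Otp passed with DESeq2 (DESeq2 adjusted p = 0.0364) and in no other setting, with edgeR adjusted p up to 0.427, and Mc4r passed in none. When adjusted over these 3 genes alone, the edgeR adjusted p was 0.0189 for Otp, 0.00889 for Mc4r and 0.771 for Sim1. The 3 genes are not one of the 27 fixed lists. That adjustment was made for the AAV comparison only and was not repeated in the other settings, so it is not counted as a pass. The labels do not say which exons are floxed, so counts over the whole gene may include transcripts of the deleted allele.

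**Figure D2:**
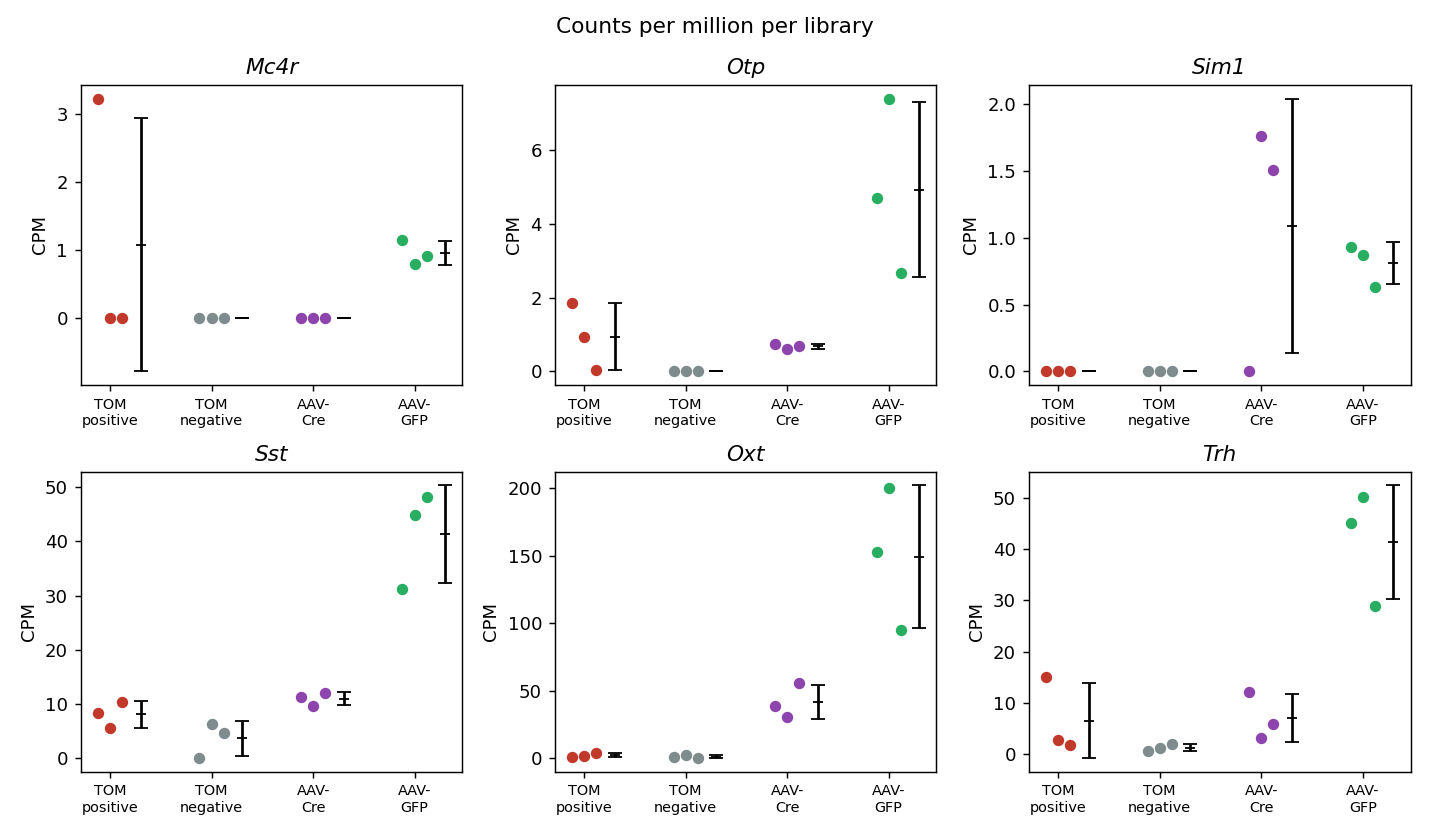
CPM of Mc4r, Otp, Sim1, Sst, Oxt and Trh in the 4 groups, with points for libraries and bars for the mean ± SD of 3 libraries. Mc4r was at 0 in each AAV-Cre library, and each of Otp, Sst, Oxt and Trh was lower in every AAV-Cre library than in every AAV-GFP library.

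PVH neuropeptide mRNAs were lower as a list after AAV-Cre. Of 16 tested, 1 fell over all genes and 5 fell when adjusted over the list alone (median log2 fold change -1.34, camera adjusted p = 0.0048, and adjusted p = 0.24 with an estimated correlation). The member that fell was Sst, the somatostatin precursor, at 11 ± 1.18 against 41.3 ± 8.95 CPM, a log2 fold change of -1.91 ± 0.36 (edgeR adjusted p = 0.0422), and its call was lost with any 1 library left out (edgeR adjusted p up to 0.18). The list itself passed in each such fit (camera adjusted p up to 0.047). Oxt, the oxytocin precursor, averaged 41.7 ± 12.8 against 149 ± 52.9 CPM (log2 fold change -1.84 ± 0.38, edgeR adjusted p = 0.051). Trh, the thyrotropin-releasing hormone precursor, averaged 7.06 ± 4.58 against 41.3 ± 11 CPM (log2 fold change -2.55 ± 0.57, edgeR adjusted p = 0.0556). Pcsk1, which encodes a protease that cleaves peptide precursors, had 0 counts in each AAV-Cre library and 48, 115 and 48 after AAV-GFP (edgeR adjusted p = 0.051). Oxt, Trh and Pcsk1 passed without a count filter (edgeR adjusted p of 0.017, 0.0237 and 0.0179) and with DESeq2 (DESeq2 adjusted p of 0.000647, 0.00108 and 0.000104), and with a replicate block they did not (edgeR adjusted p of 0.235, 0.204 and 0.281). Oxt also passed after thinning (edgeR adjusted p = 0.0496) and Pcsk1 with voom (voom adjusted p = 0.043). Without AAV-Cre replicate 1, Trh passed with a log2 fold change of -3.19 (edgeR adjusted p = 0.0401). The 6 tested peptides of other hypothalamic nuclei had a median of -1.50, and their list did not pass (camera adjusted p = 0.069), though it did with a replicate block and without AAV-GFP replicate 2 (camera adjusted p of 0.044 and 0.012). None of 20 pan-neuronal genes passed with edgeR, and their median was -0.11 and turned to 0.06 without scaling factors (camera adjusted p = 0.46). Their share of counts was 0.428% ± 0.057 after AAV-Cre and 0.332% ± 0.0515 after AAV-GFP.

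The largest falls after AAV-Cre were in ependymal, vascular and blood mRNAs, whose lists did not pass with an estimated correlation (camera adjusted p of 0.06 or more). Of 12 genes of ependymal cells, which line the ventricle, and tanycytes 8 fell, 11 when adjusted over the list alone. Their median log2 fold change was -7.06, or -6.20 with the members at 0 set to their bounds (camera adjusted p = 2.6e-10, and adjusted p = 0.06 with an estimated correlation). Rarres2 averaged 13.6 ± 4.03 against 418 ± 153 CPM (log2 fold change -4.94 ± 0.42, edgeR adjusted p = 0.0179). Spag6l, Iqca, Cdhr4, Stoml3, Nme9 and Ccdc3, the 6 genes named for the lowest fold changes, had 0 counts in each AAV-Cre library and were at least 1360-fold to 2250-fold lower. AAV-GFP replicate 1 held more of their counts than the other AAV-GFP libraries, for example 2842 against 787 and 643 for Nme9. Without it the bounds were 772-fold to 1780-fold, and those of Spag6l, Iqca, Cdhr4 and Nme9 were over 1.5 times lower, at 930, 999, 854 and 772. Spag6l encodes a protein of motile cilia. Of 12 endothelial genes 2 fell, Emcn and Bsg, and 7 when adjusted over the list alone, and Bsg had a log2 fold change of -1.94 ± 0.24 (camera adjusted p = 2.2e-05, and adjusted p = 0.16 with an estimated correlation). Of 7 blood genes 2 fell, Alas2 and Hba-a2, and when adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.036, and adjusted p = 0.78 with an estimated correlation). The blood list did not pass without AAV-Cre replicate 1 or AAV-GFP replicate 3, and after rounding was at or over the threshold without AAV-Cre replicate 3 (camera adjusted p up to 0.18 over these fits). Acta2, a smooth muscle actin gene, was the 1 of 9 mural genes that fell, at least 686-fold (list median -1.50, camera adjusted p = 0.14), and the mural list passed without AAV-Cre replicate 1 (camera adjusted p = 0.023).

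Oligodendrocyte and microglial mRNAs were higher as lists after AAV-Cre with camera at its preset correlation, and neither list passed with an estimated one (camera adjusted p of 0.44 and 0.54). Of 15 oligodendrocyte genes 4 rose, 10 when adjusted over the list alone (median log2 fold change 1.41, camera adjusted p = 1.6e-08, and adjusted p = 0.44 with an estimated correlation). Mag, a myelin glycoprotein gene, averaged 2100 ± 127 against 584 ± 122 CPM, and the list took 6.86% ± 0.77 against 3.63% ± 1.83 of counts. AAV-GFP replicate 2 stood apart with 1.58%, against 4.21% and 5.11% in AAV-GFP replicates 1 and 3, and without it the list still passed, with a median of 1.06 (camera adjusted p = 5.4e-07). Of 11 precursor genes 1 rose, Enpp6 (camera adjusted p = 0.0043, and adjusted p = 0.56 with an estimated correlation), and that list did not pass without AAV-Cre replicate 3 (camera adjusted p = 0.058, where the median went from 1.23 to 0.38). Its share of counts overlapped between the groups, since AAV-GFP replicate 2 held 0.214% and AAV-Cre replicates 1 and 2 held 0.124% and 0.144%. Of 16 microglial genes 1 rose, 3 when adjusted over the list alone (median 0.96, camera adjusted p = 7.3e-06, and adjusted p = 0.54 with an estimated correlation). It was Csf1r, the receptor that microglia need to survive, at 1530 ± 358 against 537 ± 48.3 CPM. Il1b, which encodes the cytokine interleukin 1 beta, averaged 120 ± 2.96 against 5.41 ± 2.94 CPM (log2 fold change 4.48 ± 0.52, edgeR adjusted p = 0.0202), and Ccl12, a chemokine gene, had a log2 fold change of 3.94 ± 0.68. Of 15 immediate early genes 2 rose, Egr2 and Atf3, and 8 when adjusted over the list alone (median 1.11, camera adjusted p = 4.5e-06, and adjusted p = 0.49 with an estimated correlation). Because the microglial list was higher too, it cannot be told which cells held the Il1b, Ccl12 and immediate early mRNAs. The same limit holds for the interferon list below.

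The interferon and antigen presentation list was higher with 0 of 19 members past the threshold with edgeR, and 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0065, and adjusted p = 0.78 with an estimated correlation). It did not pass without AAV-Cre replicate 2 (camera adjusted p = 0.35). The ribosomal protein list was lower with 0 of 45 members past the threshold with edgeR (median -0.85, camera adjusted p = 0.0043, and adjusted p = 0.88 with an estimated correlation). It did not pass without AAV-Cre replicate 2 or AAV-GFP replicate 3, and after rounding was at or over the threshold without AAV-Cre replicate 3 (camera adjusted p up to 0.36 over these fits). Kcna1 and Sez6l2 rose by 2.05 ± 0.36 and 1.52 ± 0.26 on the log2 scale, and Sema3c, a guidance gene, had 0 counts after AAV-Cre and was at least 225-fold lower. Their lists did not pass, with camera adjusted p of 0.17 for voltage-gated channels, 0.95 for peptide processing and 0.89 for axon guidance. The same held for hypothalamic transcription factors (0.10), energy-balance receptors (0.12), monogenic obesity genes (0.73), glutamatergic (0.81), GABAergic (0.90), monoaminergic and cholinergic neurons (0.72), synaptic vesicle release (0.23), astrocytes (0.35), the unfolded protein and heat-shock response (0.23), the p53 response (0.90) and mitochondrially encoded genes (0.35). Without a count filter, transcription factors, energy-balance receptors and voltage-gated channels passed (camera adjusted p of 0.017, 0.0096 and 0.022), the first 2 downward and the channels upward. Transcription factors also passed with a replicate block and without AAV-Cre replicate 1 or AAV-GFP replicate 1 (camera adjusted p of 0.037, 0.041 and 0.0028). Energy-balance receptors passed without AAV-Cre replicate 1, AAV-Cre replicate 3, AAV-GFP replicate 1 or AAV-GFP replicate 2 (camera adjusted p of 0.023, 5.8e-05, 0.041 and 0.019). Without AAV-GFP replicate 2, channels and, downward, mitochondrially encoded genes passed (camera adjusted p of 0.045 and 0.047). Hspa1b, a heat-shock gene with a near-identical copy, had a log2 fold change of 2.41 ± 0.49 and passed. When adjusted over the list alone, 1 monogenic obesity, 1 astrocyte, 1 p53 response and 1 peptide processing gene fell, 2 channel genes rose, and 2 heat-shock and unfolded protein genes rose and 1 fell. Mitochondrially encoded genes took 7.20% of counts in AAV-GFP replicate 3 and 1.44% to 2.63% in the other AAV libraries. In the glutamatergic, GABAergic, pan-neuronal and p53 lists the median was under 0 and the test pointed up.

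In all, 400 of 15408 genes passed with edgeR, 97 higher and 303 lower after AAV-Cre, and 185 of the lower genes had 0 counts in every AAV-Cre library. Genes with no count numbered 41062, 39472 and 38821 in the AAV-Cre libraries and 35031, 34294 and 31907 in the AAV-GFP libraries. Whether this reflects lower expression or few starting molecules was not tested. The groups did not overlap for 28.5% of genes, where chance gives 10%. Without scaling factors 127 were higher and 241 lower, with a median shift of 0.16 on the log2 scale. Every gene call of this comparison was lost without AAV-GFP replicate 1 or without AAV-GFP replicate 3, where edgeR passed 0 genes, 2609 and 2342 genes had an unadjusted p under 0.05 and DESeq2 passed 1303 and 1110. The count was 2 without AAV-GFP replicate 2 and 122 without AAV-Cre replicate 2, and with all libraries it was 712 without a count filter, 1531 with DESeq2 and 245 against a 1.5-fold change. With a replicate block, edgeR passed 0 genes. Of 27 lists 10 passed, and with an estimated correlation 0 passed after adjustment, with 3 at an unadjusted p under 0.05 and 8 past the threshold with fry. Only 5 of the 10 passed with fry. It lost microglia, oligodendrocyte precursors, immediate early, interferon and ribosomal protein genes (fry adjusted p of 0.18, 0.27, 0.061, 0.54 and 0.28). It gained, downward, transcription factors, peptides of other nuclei and mural genes (fry adjusted p of 0.036, 0.038 and 0.0049). Virus, reporter and Otp deletion differ together between these groups.

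**Figure D3:**
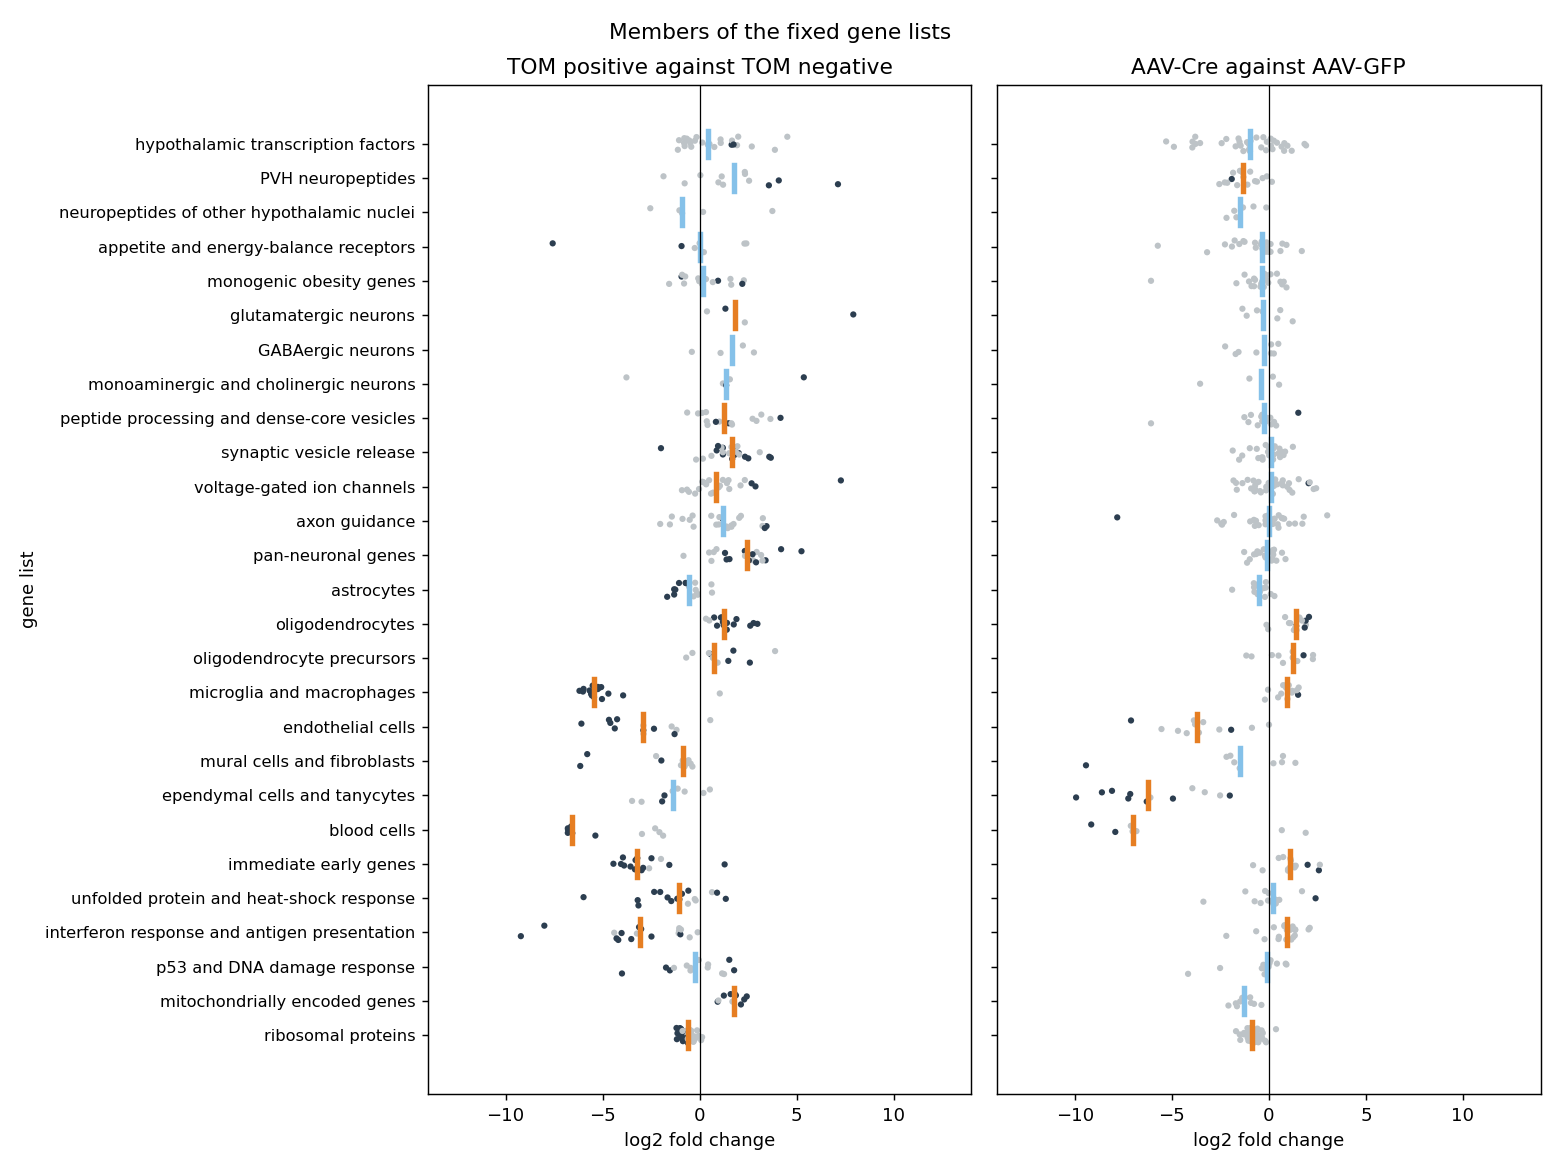
Log2 fold change of each tested member of the 27 gene lists in both comparisons, with dark points for genes that passed with edgeR, genes with 0 counts in a whole group drawn at their bound, and bars for list medians, orange where camera passed. The microglial median was -5.44 in the TOM comparison and 0.96 in the AAV comparison.

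The third comparison asked whether genes that set TOM positive cells apart differed after AAV-Cre. The 1561 tested genes that were higher in TOM positive cells were higher as a set after AAV-Cre (median log2 fold change 0.26, camera adjusted p = 2.4e-11 over both sets, and unadjusted p = 0.0011 with an estimated correlation). The 1867 tested genes that were lower in TOM positive cells had a median of -0.12, while the test pointed up and did not pass (camera adjusted p = 0.15). That set passed, with an unadjusted camera p of 0.049 each, without AAV-Cre replicate 1, AAV-Cre replicate 3 or AAV-GFP replicate 3, and of 0.014 each without TOM negative replicate 1 or TOM negative replicate 2. It also passed without scaling factors and without a count filter, with unadjusted camera p of 0.03 and 0.0087. In all, the set gained a call in 6 settings that kept the sign of its median, not all named here, and its median turned in 2. Among 13975 genes tested in both comparisons, 59 were higher in both, where independent lists give 10.7, and 1, Ptges3, was higher in TOM positive and lower after AAV-Cre, where independent lists give 19.5. Ptges3, named after its values were seen, had an AAV log2 fold change of -1.67. Oligodendrocyte list genes among the 59 were Ermn, Mal, Mag and Ugt8a, all members of the list fixed before, and Enpp6 is a precursor list gene. That list holds only 15 genes, so other genes of these cells among the 59 are not counted. The list took 10.9% of counts in TOM positive and 2.8% in TOM negative libraries, and 6.86% after AAV-Cre and 3.63% after AAV-GFP. A larger oligodendrocyte content of both first groups could therefore give part or all of the overlap, which was not tested. There were 19 genes lower in TOM positive and higher after AAV-Cre, where independent lists give 12.8, and 34 lower in both, where they give 23.4. Csf1r of the microglial list was among the 19. Rarres2 and Vim of the ependymal list, Bsg of the endothelial list and Alas2 and Hba-a2 of the blood list were among the 34. Differences in cell content could enter these numbers too, which was not tested. No library was shared by the 2 comparisons, but the first group of each was sorted as TOM positive. Effects of reporter, Cre or sort common to both cannot be told apart from shared expression.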

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

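Totals without scaling factors, thinning and the set without glial, vascular, ependymal and blood genes were chosen after seeing the data, and the cause of the changes below was not tested unless the setting itself shows it. In the TOM comparison the count of 3635 genes went to 2177 against a 1.5-fold change, a stricter test, and ranged from 1511 to 3547 with 1 library left out. In the AAV comparison the count of 400 went to 712 without a count filter, 1531 with DESeq2 and 245 against a 1.5-fold change, and ranged from 0 to 296 with 1 library left out, where fewer libraries were fitted. With edgeR 0 genes passed without AAV-GFP replicate 1 or 3, where DESeq2 passed 1303 and 1110 and 2609 and 2342 had an unadjusted p under 0.05. With an estimated correlation 0 lists passed in both comparisons, with lowest adjusted p of 0.12 and 0.06. Counts of lists stayed within 1.5 times of 16 and 10 under the other settings. With fry, the lists that passed held all 16 of the TOM comparison but only 5 of the 10 of the AAV comparison. The set higher in TOM positive cells stayed past the threshold with medians from 0.22 to 0.36. Leaving out the glial, vascular, ependymal and blood list genes does not remove other genes of those cells from that set.

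Same-numbered libraries did not deviate together (correlations of deviations -0.031, -0.014 and 0.025 in the TOM and -0.07, -0.07 and -0.065 in the AAV comparison), so the numbers are not taken to pair samples. With the replicate block, 1987 genes passed in the TOM comparison and 0 in the AAV comparison with edgeR, where 2013 had an unadjusted p under 0.05 and DESeq2 with the block passed 1504. The block leaves fewer residual degrees of freedom.

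Direction turned for genes that had not passed. Sim1 after AAV-Cre went to -0.31 with the replicate block, -0.10 with voom and -0.11 without AAV-Cre replicate 2. With 1 library left out, Slc17a5 ranged from -0.09, without AAV-Cre replicate 1, to 0.70. The median of the set lower in TOM positive cells, whose test pointed up in the full comparison, was 0.12 without scaling factors, where all genes moved by a median of 0.16, and ranged from -0.26 to 0.01, without AAV-GFP replicate 3, with 1 library left out. That crossing of 0 says nothing about the set. Of the other values of named genes, 264 lost and 60 gained a call and 2097 kept direction and side of the threshold.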

Other observations

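The sex-linked genes below, and the tests of pan-neuronal genes, other peptides, thinning, oligodendrocyte genes, the ependymal share, expected Mc4r counts and correlations, were chosen after the result was seen. Xist, the transcript of the inactive X chromosome of female mice, had 105 to 573 counts in each TOM library and 0 in each AAV library, and Eif2s3y, a gene of the Y chromosome, had 0 in each TOM library and 210 to 429 in each AAV library. Sex is not in the labels. By these transcripts, the 2 comparisons differ in sex as well as in age and tissue.

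PVH neuropeptide mRNAs were lower as a list after AAV-Cre with a preset correlation and did not pass with an estimated one (camera adjusted p of 0.0048 and 0.24). Over all genes 1 of 16 members passed with edgeR, and its call was lost with any 1 library left out. A smaller share of neurons as a whole is argued against, since pan-neuronal genes had a median log2 fold change of -0.11 with an SD of 0.59 over genes, against -1.34 for the peptides. These genes cannot test for a smaller share of the neurons that make the peptides, because they count all neurons together. At the preset correlation, a single deciding library is argued against for the list, whose camera p was at most 0.014 with any 1 library left out. That limits the point, since at this correlation splits that mix AAV-Cre and AAV-GFP libraries passed up to 16 lists. A fall of peptide mRNA that is not specific to PVH peptides stays open and is consistent with the median of -1.50 over 6 peptides of other nuclei. Otp deletion is a biological hypothesis that virus and reporter keep untested.

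Ependymal mRNAs were nearly missing after AAV-Cre, in a list that did not pass with an estimated correlation (camera adjusted p = 0.06). Their mean share of counts was 0.00478% after AAV-Cre and 0.139% after AAV-GFP. It was 0.0051% in TOM positive and 0.0102% in TOM negative libraries, which differ in age and tissue. A loss after AAV-Cre therefore cannot be told apart from an excess in the AAV-GFP sort. Lower depth is argued against, since 8 ependymal genes still passed after thinning to equal depth. Thinning equalizes read totals only. It cannot test for fewer starting molecules in the AAV-Cre libraries, which held more genes with no count than the AAV-GFP libraries. A lower share of all non-neuronal cells is argued against by oligodendrocyte genes, with a median log2 fold change of 1.41 and an SD of 0.66 over genes. Reporter, virus or sort cannot be told apart from Otp deletion, because all 3 AAV-Cre libraries lay below every AAV-GFP library and the groups differ in all of these. Which cells took up each virus may differ, and no library here separates that.

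Mc4r was counted in 1 of 3 TOM positive libraries. Too few reads are argued against, since at the rate of replicate 1 the other libraries would hold 94.9 and 98.9 counts and held 0. A TOM negative library under a TOM positive label is argued against, since replicates 2 and 3 each correlated more with both other TOM positive libraries than with any TOM negative one, by at least 0.072. Few starting molecules per library is consistent with 497 genes that had at least 63 counts in 1 TOM positive library and 0 in the others, against 36 such genes in the TOM negative group. No biological explanation was tested.

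Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05, and other splits reached the real value only for the AAV gene lists, so that 1 of the 10 splits, the real one, gave each of the other results. In the TOM comparison the real split gave 3635 genes and 16 lists, and the highest other split 0 genes and 12 lists. In the AAV comparison it gave 400 genes and the highest other 0, and with 10 lists it was matched or passed by other splits, 5 of the 10 in all, up to 16 lists. The other splits passed 0 genes with edgeR, with 99 to 400 genes in the TOM and 177 to 580 in the AAV comparison at an unadjusted p under 0.05, and no other tool was run on them. For the set higher in TOM positive cells, -log10 of the camera p was 10.9 in the real split and at most 5.9 in the others.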
